A study of Mus musculus with 5 samples.

How the data were processed

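Gene expression was measured by RNA sequencing of polyadenylated RNA from mouse glioma cells sorted on tdTomato out of co-culture with olfactory bulb neurons, in 2 libraries without and 3 with IGF-1. The deposited values are raw counts of reads per gene symbol, with 1 table per library and 29495 genes in each, and every gene has at least 1 count over the 5 libraries. Per the submitters' processing notes, the tools were cutadapt 3.4, STAR 2.7.9a, featureCounts 2.0.1 and DESeq2 1.28.1, and the genome build was GRCm39. The notes give neither the role and settings of each tool nor the gene annotation, and whether strand or multiply mapped reads were used in counting is not given in the sources used here. Reads of paralogs, pseudogenes and overlapping genes can therefore be shared in these counts. Per the labels' protocols, the neurons were plated in a medium that contained insulin and serum, and later media held serum and B27, so the control cells were not free of growth factors.

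Groups were taken from the titles and treatment labels. The numbers 1 to 5 name samples and are not shared between the groups, so no library was paired with another. The labels give no batch. Libraries held 16944315 to 20144181 counts, and 23560 to 24059 genes had a count. Every pair of libraries of 1 group differed by more than sampling noise in a chi-square test over genes with at least 20 counts summed over both. The statistic per degree of freedom was 2.29 for the controls, 2.33 for IGF-1 replicates 3 and 4, and 13.4 and 13.5 for replicate 5 against them. All 5 libraries were kept as separate samples, although such a spread can also be technical. The biological coefficient of variation was 0.0774 with all libraries and 0.0324 without IGF-1 replicate 5.

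Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 15919 genes, and libraries were scaled with TMM factors. The 3 IGF-1 libraries were compared with the 2 controls by the quasi-likelihood F-test, which is two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are scaled by the TMM factors, and means are given with their SD.

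The genes named in the text followed a rule written before the data were examined. It takes, among genes past the threshold with a mean of at least 1 CPM whose values do not overlap between the groups, the 12 with the largest rise and the 12 with the largest fall, leaving out predicted, clone-named, immunoglobulin and pseudogene symbols. It adds up to 4 called members of each gene list with the smallest adjusted p, or the 2 most abundant members where none was called. Igf1r, Insr, Irs1, Irs2, Igf1, Ccnd1, Mki67, Pdgfra, Olig2, Gfap, Trp53 and Nf1 are given whatever their result. Some genes that the rule names are not reported here. Txnip and Junb, the counts of single markers, and the genes named in the closing section were chosen after their values were seen.

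In addition, 28 gene lists were written before the data were examined. They cover growth factor signalling, cell cycle, metabolism, ribosomes, stress, p53 targets, matrix, synapse and glial state, other cell types of the olfactory bulb culture, and mitochondrially encoded genes. Of their 671 genes 657 were found, 6 of them through an older symbol, and 575 passed the filter. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom log2-CPM with a preset correlation of 0.01, adjusted over lists. Camera with a correlation estimated per list and fry were alternatives. Members past the threshold were also counted after adjustment over the list alone.

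The alternatives fixed before the data were examined were RLE factors, total counts without factors, no filter on low counts, DESeq2 1.42.0, limma-voom and each library left out in turn. Those added after seeing the data were sample quality weights, an offset for the trend of log2-CPM on transcript length in each library, DESeq2 with each library left out, and estimated correlations and fry without IGF-1 replicate 5. With 1 control left out, the remaining control is assumed to vary like the IGF-1 group. Transcript lengths came from principal transcripts of a mouse annotation of another build (GRCm38), matched by symbol for 98.9% of tested genes. Coordinates are not given because the builds differ.

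The procedure was tested on simulated data, drawn from the means and library sizes of the real libraries with 200 genes changed. With all 5 libraries and 15585 genes, 59% of 100 genes changed 1.5-fold and 83% of 100 changed 2-fold were recovered, with 6 false calls. Without IGF-1 replicate 5 and with 15378 genes, 80% and 92% were recovered, with 9 false calls. A list whose members all shifted equally, by more than the median of any list called in the real libraries, was called in both. Of 25 unshifted lists 0 were called. Smaller or uneven shifts of a list were not simulated. Genes were drawn independently of each other, and no simulated library stood apart as IGF-1 replicate 5 does. The simulation therefore cannot show how often camera calls unshifted lists whose members are correlated, as in the real libraries. Figures were drawn with matplotlib 3.10.9.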

Results

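The libraries came from mouse glioma cells lacking p53 and NF1 and carrying the red fluorescent protein tdTomato, from a tumor model on a mixed CD-1 and C57BL/6 background. The cells were grown together with olfactory bulb neurons of C57BL/6 pups and then separated from them by fluorescence-activated sorting on tdTomato. RNA was polyadenylated and sequenced in 2 libraries of unstimulated co-cultured cells (control replicates 1 and 2) and 3 libraries of cells given 20 ng/mL of insulin-like growth factor 1 (IGF-1) overnight (IGF-1 replicates 3, 4 and 5). Total counts were 17365697 and 16944315 in the controls and 18359421, 19036906 and 20144181 with IGF-1. The labels do not say that the libraries came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. IGF-1 replicate 5 stood apart from the other 4 libraries on the first principal component, which held 35.2% of the variance. On the second (26.1%), IGF-1 replicates 3 and 4 lay at -17.8 and -21.1. Replicate 5, at 14.0, lay there beside the controls, at 11.4 and 13.5. Over genes of at least 10 CPM (counts scaled to a common library total), the SD of the log2 difference was 0.12 between the controls, 0.11 between IGF-1 replicates 3 and 4, and 0.22 between replicate 5 and either of them.

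The comparison asks which transcripts of co-cultured glioma cells differ after IGF-1. Among the genes that rose most were Egr3, a transcription factor of the early growth response family, and Srf, the serum response factor. Egr3 rose from 16.8 ± 1.59 CPM (SD, n = 2) to 41.7 ± 4.73 (SD, n = 3), a log2 fold change of 1.31 with an SE of 0.12. Srf rose from 36.3 ± 0.994 to 67.7 ± 1.99 CPM, by 0.90 on the log2 scale (SE 0.07). The deepest falls among the named genes were those of Ccng2, the growth-inhibiting cyclin G2, and Crebrf, a regulator of the stress factor CREB3. Ccng2 went from 46.1 ± 2.20 to 17.7 ± 1.57 CPM and fell by 1.38 (SE 0.10), and Crebrf went from 70.5 ± 1.4 to 28.0 ± 2.93 CPM and fell by 1.33 (SE 0.09). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00206 for Egr3, 0.0011 for Srf, and 4.42e-04 for Ccng2 and Crebrf.

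The other rises named by the rule fixed in advance lay between 0.87 and 1.17 on the log2 scale. They included Sertad1, which binds the cyclin D kinase CDK4 (1.17), Areg, the epidermal growth factor receptor ligand amphiregulin (1.11), and Nab2, a corepressor of EGR proteins (1.03). Klf16 (1.10), Ier5l (1.05), Hivep3 (0.95), the AP-1 subunit gene Fosl2 (0.93), the chromatin protein gene Hmga2 (0.88), Rasl11a (0.88) and the secreted factor gene Metrnl (0.87) completed the set. Among the falls were Slitrk6, a neuronal-type transmembrane protein gene (-1.29), Snai2, a transcription factor of epithelial-mesenchymal transition (-1.13), and Bmf, a pro-apoptotic BH3-only gene (-1.02). Gpr146 (-0.99), the ubiquitin ligase gene Fbxo32 (-0.98), the repressor gene Hbp1 (-0.86), Klf15 (-0.81), Zfp874b (-0.78), the glycogen-targeting phosphatase subunit gene Ppp1r3c (-0.75) and Kctd4 (-0.75) also fell. Zfp874b has close paralogs, and its reads could be shared with them. Areg, at 2.54 CPM in the controls, was the least firmly called of these genes, with an adjusted p of 0.0496.

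**Figure D1:**
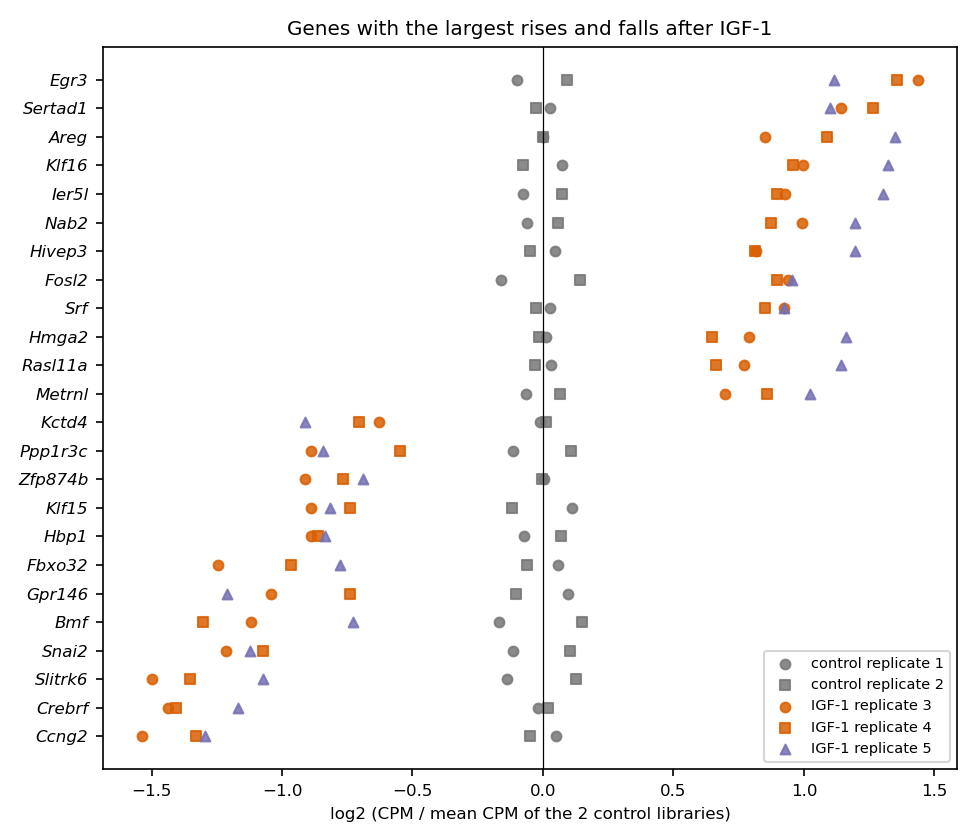
Expression of the 12 genes with the largest rises and the 12 with the largest falls, as log2 of each library's CPM over the mean CPM of the control replicates (x axis), with 1 point per library. The rule took only genes whose values do not overlap between the groups, so the 3 IGF-1 libraries lie on 1 side of both controls by selection. IGF-1 replicate 5 is drawn as triangles.

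Of 15919 genes tested, 109 were higher and 54 lower with IGF-1 at an adjusted p under 0.05. The log2 changes of these 163 genes ranged in size from 0.31 to 1.4, with a median of 0.52 for the higher and -0.62 for the lower genes, and 13 exceeded 2-fold. Without IGF-1 replicate 5, 855 genes were higher and 569 lower of 15573 tested, among them all 109 and all 54, and DESeq2 called 316 and 146. With control replicate 1 left out, edgeR called 0 genes higher and 2 lower, Ccng2 and Crebrf, against 680 higher and 471 lower at an unadjusted p under 0.05 and 30 and 7 called by DESeq2. Leaving out control replicate 2 likewise gave 0 and 2, the same 2 genes, against 546 and 409 unadjusted and 22 and 9 by DESeq2, and leaving out IGF-1 replicate 3 or 4 gave 29 and 9, or 35 and 18 (99 and 35, or 92 and 41, by DESeq2).

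Some of the genes that FOXO transcription factors activate, and that insulin-like signals are known to repress, fell. Of 24 tested members of this list 0 rose and 6 fell by edgeR, with 0 and 11 unadjusted and 0 and 7 by DESeq2, and 12 fell without IGF-1 replicate 5. Adjusted over the list alone 0 rose and 9 fell, and the median log2 change was -0.17. Besides Ccng2, Fbxo32 and Klf15 these were Klhl24 (-0.67), Txnip (-0.58), a brake on glucose uptake, and Irs2 (-0.49), an adaptor of the insulin and IGF-1 receptors. Camera with its preset correlation placed the list lower than other genes (adjusted p = 5.53e-09; adjusted p = 0.981 with an estimated correlation). Fry gave an adjusted p of 0.163 for 1 direction and 0.00581 for change in either. In the list of IGF receptor pathway genes, which also holds Irs2, 0 of 27 rose and 2 fell by edgeR, with 3 and 3 unadjusted. DESeq2 called 1 higher and 3 lower, as edgeR called 2 higher and 3 lower without IGF-1 replicate 5. The 2 falls were those of the adaptors Irs1, from 53.6 ± 0.188 to 34.3 ± 1.64 CPM (log2 -0.64, SE 0.08, adjusted p = 0.0055), and Irs2, from 265 ± 4.96 to 189 ± 13.4 CPM (SE 0.07, adjusted p = 0.0137). Adjusted over the list alone, 0 rose and 3 fell. That list as a whole was not called (camera adjusted p = 0.981, direction down, although its median of 0.02 was above 0), while fry's test for change in either direction gave an adjusted p of 0.00206. The receptor genes Igf1r (0.12, adjusted p = 0.727) and Insr (0.16, adjusted p = 0.446), and Igf1 itself (-0.39, adjusted p = 0.673), did not pass the test. Without IGF-1 replicate 5 they were at -0.05, 0.09 and -0.05, in that order, and did not pass either.

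Among immediate early and ERK feedback genes, some rose and some fell. Of 26 tested, 3 rose and 3 fell, or 7 and 8 adjusted over the list alone, and 7 and 11 without IGF-1 replicate 5. Egr3, Fosl2 and Ccnd1, the gene of cyclin D1, rose, Ccnd1 from 1138 ± 4.40 to 1458 ± 76.9 CPM (log2 0.36, SE 0.07, adjusted p = 0.0385). Egr1 fell from 333 ± 7.08 to 207 ± 22.3 CPM (log2 -0.68, SE 0.09, adjusted p = 0.0067), Spry1, an inhibitor of growth factor signalling, fell by 0.52, and Junb fell by 0.57. Fry's test for change in either direction gave an adjusted p of 0.0025, while camera did not call a direction (adjusted p = 0.902, down, with a median of -0.11 and a mean of 0.03). Among 16 p53 target genes 2 rose, the cell cycle inhibitor gene Cdkn1a (0.48) and the nuclease gene Aen (0.43), and 0 fell by edgeR and DESeq2, with 5 higher and 3 lower unadjusted, and 5 and 2 of 15 called without IGF-1 replicate 5. Adjusted over the list alone 4 rose and 2 fell, and fry's mixed test gave an adjusted p of 0.00119 (camera adjusted p = 0.569). The cells are described as lacking p53, so these changes cannot be read as p53 activity.

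Cell cycle genes gave few calls. Of 32 genes of G1/S and DNA replication edgeR and DESeq2 called 0, also adjusted over the list alone, and 1 was lower and 0 higher at an unadjusted p under 0.05, as called by edgeR without IGF-1 replicate 5. The median was -0.04 (camera adjusted p = 0.581), with Rrm1 at -0.10 and Mcm6 at -0.07. Of 35 genes of G2/M and mitosis 0 rose and 1 fell by edgeR and DESeq2, also adjusted over the list alone, with 0 and 5 unadjusted. The fall was that of Cenpa, the centromeric histone gene (-0.39). Camera called that list lower (median -0.08, adjusted p = 7.14e-04; adjusted p = 0.981 with an estimated correlation), but not without IGF-1 replicate 5 (median -0.03, adjusted p = 0.104, 4 members lower). The proliferation marker Mki67 was at 835 ± 3.06 CPM in the controls and 786 ± 52.8 with IGF-1 (log2 -0.09, adjusted p = 0.65).

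Some genes of cholesterol synthesis rose. Of 25 tested 3 rose and 0 fell by edgeR and DESeq2, with 12 and 0 unadjusted and 7 and 0 adjusted over the list alone. The list had 20 of 25 log2 changes above 0 and a median of 0.17. Among them Hsd17b7, an enzyme gene of the pathway, rose from 32.7 ± 0.226 to 45.9 ± 3.13 CPM (log2 0.49, SE 0.09, adjusted p = 0.0306). Camera called the list higher (adjusted p = 1.04e-06; adjusted p = 0.981 with an estimated correlation). Fry gave an adjusted p of 0.657 for 1 direction and 0.0212 for change in either. The list's median was 0.28, 0.22 and 0.05 in IGF-1 replicates 3, 4 and 5, and without replicate 5 13 members rose. Fatty acid synthesis genes did not pass with all libraries: edgeR and DESeq2 called 0 of 16, 0 were under 0.05 unadjusted, and 0 passed adjusted over the list alone (median 0.01, mean -0.01, camera adjusted p = 0.902), with Fasn at 0.15 and Scd2 at 0.09, and 2 were higher without replicate 5.

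Of 28 genes of glycolysis and hypoxia 1 rose and 0 fell by edgeR, with 2 and 1 unadjusted, 2 and 0 by DESeq2, 2 and 0 adjusted over the list alone, and 2 and 0 without IGF-1 replicate 5. The gene that rose was Pfkfb3, whose enzyme makes the activator of phosphofructokinase, and it rose from 28.8 ± 0.989 to 51.9 ± 0.505 CPM (log2 0.85, SE 0.08, adjusted p = 0.00206). The list's median was 0.01 (camera adjusted p = 0.677; adjusted p = 0.0181 by fry's test for change in either direction). Of 34 genes of ATF4 and amino acid supply edgeR called 0, also adjusted over the list alone; 1 was higher at an unadjusted p under 0.05, and DESeq2 called 1 higher. Psat1, of serine synthesis, was at -0.14 and Aars, an aminoacyl-tRNA synthetase gene, at -0.05. The list's median turned direction with IGF-1 replicate 5: -0.08 with all libraries (adjusted p = 0.194) and 0.05 without it, when 8 members rose and the list was called higher (adjusted p = 0.00178; adjusted p = 0.635 with an estimated correlation). Camera called it lower without IGF-1 replicate 3 (median -0.17, adjusted p = 0.0293) and without replicate 4 (median -0.20, adjusted p = 9.04e-05).

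Camera placed nucleolar genes of ribosome biogenesis higher and genes of cytosolic ribosomal proteins lower than other genes. Of 30 ribosome biogenesis genes 2 rose and 0 fell by edgeR, with 9 and 0 unadjusted, 5 and 0 by DESeq2, and 8 and 0 adjusted over the list alone. Rrs1 rose from 65.0 ± 0.822 to 91.2 ± 7.24 CPM (log2 0.49, SE 0.08, adjusted p = 0.0217) and Nop2 from 97.1 ± 0.381 to 123 ± 3.97 CPM (log2 0.35, SE 0.06, adjusted p = 0.0342). The median was 0.09 (camera adjusted p = 5.75e-04; adjusted p = 0.981 with an estimated correlation). It was 0.17 in replicate 3, 0.16 in replicate 4 and -0.07 in replicate 5. Without replicate 3 or 4 the list was not called (adjusted p = 0.0688 and 0.071), and without replicate 5 14 members rose. Of 50 ribosomal protein genes edgeR and DESeq2 called 0, also adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. All 50 log2 changes were below 0 (median -0.18), with Rps2 at -0.18 and Rps4x at -0.19. Camera gave an adjusted p of 1.43e-09 (adjusted p = 0.981 with an estimated correlation). The list's medians per IGF-1 library were -0.04, -0.07 and -0.46 in replicates 3, 4 and 5, and without replicate 5 the median was -0.06 and 5 members were lower. Ribosomal protein genes have many processed pseudogenes, with which their reads could be shared.

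**Figure D2:**
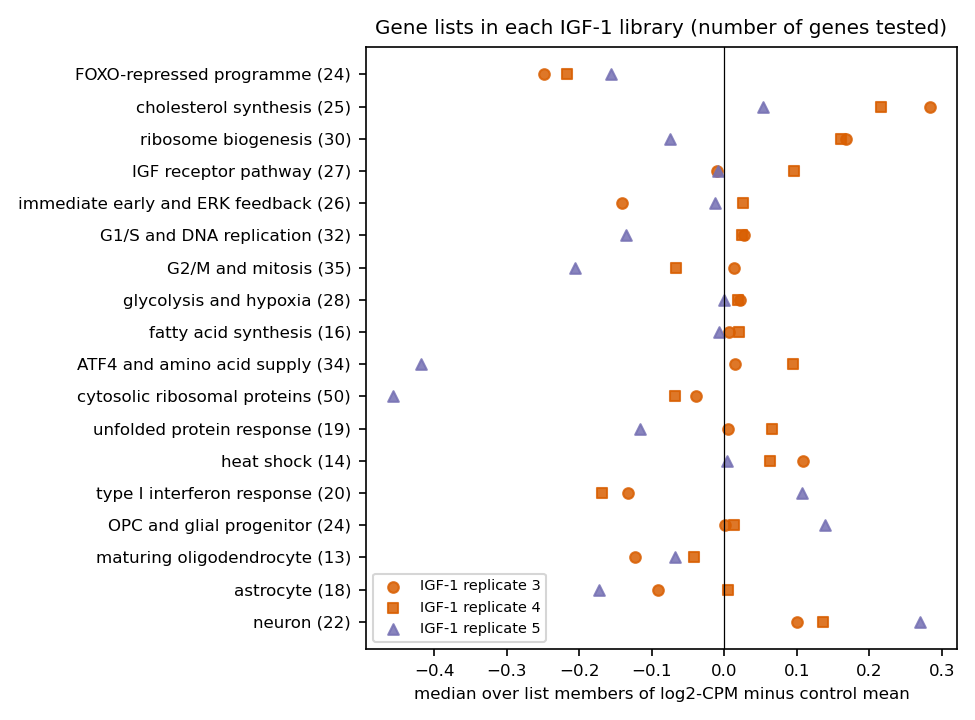
Median over the tested members of 18 gene lists of each IGF-1 library's log2-CPM minus the control mean (x axis), with 1 point per library and the number of genes tested in parentheses. The lists of FOXO and cholesterol genes lie on 1 side of 0 in all 3 libraries. So do those of ribosomal protein, heat shock, progenitor, maturing oligodendrocyte and neuronal genes. Of these further lists, camera called only that of ribosomal proteins with all libraries. IGF-1 replicate 5, drawn as triangles, lies apart for ribosomal protein genes (-0.46) and for genes of ATF4 and amino acid supply (-0.42).

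Stress, inflammatory and matrix genes did not pass as lists or as single members with all libraries. EdgeR and DESeq2 called 0 members of the unfolded protein response (19 tested, median -0.01), heat shock (14, 0.07), type I interferon (20, -0.03), inflammatory NF-kB (15, -0.12), extracellular matrix (32, 0.02) and postsynaptic (23, 0.02) lists. At an unadjusted p under 0.05, these lists held 2 lower, 3 higher, 2 lower, 2 lower, 1 higher and 2 lower, and 1 lower members, in that order. Adjusted over the list alone, 1 heat shock gene was higher, and 0 members of the other 5 lists passed. Camera adjusted p was 0.902, 0.581, 0.359, 0.902, 0.902 and 0.9999 for the 6 lists. The chaperone genes Hsp90ab1 (-0.07) and Hspa8, Canx (-0.07) and Calr (-0.01), the interferon genes Xaf1 (-0.04) and Irf9 (-0.03), Csf1 (-0.17), Nfkb1 (0.13), Vim (0.10), Col11a1 (-0.03), Nlgn2 (0.02) and Gria4 (0.13) were their most abundant members. Without replicate 5, edgeR called 4 heat shock genes higher, 3 interferon, 2 NF-kB, 2 postsynaptic and 1 unfolded protein response genes lower, and 2 matrix genes higher and 1 lower. Camera then called heat shock higher (adjusted p = 0.0104, or 0.519 with an estimated correlation). It called interferon genes lower (adjusted p = 4.44e-04, or 0.338 with an estimated correlation). The medians of the 6 lists without replicate 5 were 0.03, 0.08, -0.14, -0.08, 0.01 and -0.08, in the order above.

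Few markers of glial state passed the test with all libraries. Among 24 markers of oligodendrocyte progenitors edgeR called 0, DESeq2 called 1 higher, 4 were higher and 2 lower unadjusted, and 1 was higher adjusted over the list alone (median 0.07, camera adjusted p = 0.359). Without IGF-1 replicate 5, 4 of them were higher and 2 lower, and 1 and 2 of the astrocyte genes and 0 and 1 of the maturing oligodendrocyte genes. Ptprz1 (0.02), Sox10 (0.11), the growth factor receptor gene Pdgfra (0.06, adjusted p = 0.823) and the lineage factor gene Olig2 (0.16, adjusted p = 0.377) were among those not called. Without IGF-1 replicate 5 these genes were at 0.01, 0.05, -0.05 and 0.12, and the progenitor list's median was 0.006. Of 13 maturing oligodendrocyte genes edgeR and DESeq2 called 0, and 0 were under 0.05 unadjusted or passed adjusted over the list alone (median -0.06, adjusted p = 0.506), with Cldn11 at -0.09. Camera called that list lower without control replicate 2 (median -0.09, adjusted p = 0.0497). Of 18 astrocyte genes 0 rose and 1 fell by edgeR and DESeq2, also adjusted over the list alone, with 1 and 2 unadjusted. The fall was that of F3, the tissue factor gene (-0.44, adjusted p = 0.0184). The list was not called (camera adjusted p = 0.581), and Gfap was at -0.35 (adjusted p = 0.487), or at -0.18 without IGF-1 replicate 5. Trp53 was read at 87.7 ± 1.5 CPM in the controls and 82.7 ± 0.462 with IGF-1, and Nf1 at 131 ± 2.10 and 130 ± 3.59 CPM. Counts over a whole gene cannot show the loss of part of it, so these levels do not check the genotype.

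Transcripts of cells that the sort was meant to remove were scarce. The neuronal nuclear protein gene Rbfox3 had 0 to 1 counts per library and Snap25 9 to 21. Of microglial genes Ptprc had 1 to 7, Csf1r 3 to 5 and Tyrobp 0 to 2 counts, and of endothelial genes Cdh5 had 0 to 3 and Pecam1 6 to 23. Of 33 neuronal genes in the files 14 averaged under 1 CPM, but Map2 averaged 493 CPM, so the list also holds genes abundant in every library here. EdgeR and DESeq2 called 0 members of the lists of neurons (22 tested), olfactory ensheathing glia (8), microglia (5), endothelium (6), fibroblasts and mural cells (7) and mitochondrially encoded genes (13), also adjusted over each list alone. Unadjusted, 2 neuronal genes and 1 fibroblast or mural gene were higher, and 0 genes of the other 4 lists passed. Neuronal markers, of which Map2 (-0.07) and Reln (0.12) were the most abundant, had a median of 0.22 with 19 of 22 above 0 (camera adjusted p = 0.0836), and medians of 0.10, 0.14 and 0.27 in IGF-1 replicates 3, 4 and 5. Camera called this list higher without control replicate 1 (adjusted p = 0.0194) and without IGF-1 replicate 3 (adjusted p = 0.0293), but not without any of the other 3 libraries, nor with an estimated correlation (adjusted p = 0.981). The other medians were -0.03, 0.01, 0.05, 0.07 and 0.02 (camera adjusted p = 0.902, 0.902, 0.902, 0.581 and 0.902). Cdh2 (-0.03), Cd68 (-0.28), Ramp2 (0.12), Flt1 (-0.01), Cspg4 (0.33), Col3a1 (0.07), mt-Co1 (-0.02) and mt-Cytb (-0.09) were among their most abundant members. Without IGF-1 replicate 5, camera called the mitochondrially encoded list lower, with 3 members lower (adjusted p = 0.00973; adjusted p = 0.635 with an estimated correlation), and edgeR called 2 neuronal and 1 fibroblast or mural genes higher and 1 ensheathing glia gene lower. Of red blood cell genes only Alas2 was abundant enough to test (0.25), so that list was not tested.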

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

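Quality weights, the transcript length offset, DESeq2 with libraries left out, and estimated correlations and fry without IGF-1 replicate 5 were chosen after seeing the data. All 163 called genes kept their direction in each of the 12 alternative fits. These fits reuse the libraries in which the genes were called, so the kept direction is not independent evidence. RLE factors gave 109 higher and 53 lower genes, total counts 84 and 51, and limma-voom 83 and 49. More passed with no low-count filter (385 and 221), with DESeq2 (180 higher, 75 lower), with sample quality weights (480 and 331) and with the length offset (174 and 88). Leaving out each library in turn gave 0 to 855 higher and 2 to 569 lower genes. The low ends came without control replicate 1 or 2, where 1 control remains, and the high ends without IGF-1 replicate 5, whose quality weight was 0.292 against 1.34 to 1.39 for the others. For gene lists, 5 were called, and 5 to 8 with each library left out in turn, 8 without IGF-1 replicate 5. With correlations estimated per list 0 were called, with or without that library. With all libraries fry's directional test called 0, and its test for change in either direction 6; without IGF-1 replicate 5 the directional test called 2, ribosome biogenesis and heat shock (adjusted p = 0.0486 for both). The median of the ATF4 and amino acid supply list on the voom scale was -0.203 to 0.0484 with each library left out, turning to 0.0484 without IGF-1 replicate 5, where it was called higher, while it was called lower without replicate 3 or 4. That of the mitochondrially encoded list was -0.0625 to 0.0974, turning to -0.0625 without that library. Explanations tested for the former are among the other observations; for the latter the cause was not tested. No paired analysis was possible because the sample numbers are not shared between the groups. In simulated data 59% of 1.5-fold changes were recovered with all libraries and 80% without IGF-1 replicate 5.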

Other observations

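The test of the ATF4 and amino acid supply genes for carried-over neurons was chosen after the results were seen. So was that of ribosomal protein genes without IGF-1 replicate 5. Genes of the actin cytoskeleton that the serum response factor SRF is known to activate were among the rises. Fhl3 rose by 0.82 on the log2 scale, Lima1 by 0.53, Zyx, the gene of the focal adhesion protein zyxin, by 0.49, Vcl, the vinculin gene, by 0.37 and Wdr1 by 0.34, beside Srf itself at 0.90. Of 35 tested genes in a list of SRF targets 8 were higher and 1, Egr1, was lower. That list was written with the calls in view, so no test of it on these libraries is independent evidence.

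Some genes with symbols of Zfp and a number, most of them zinc finger transcription factors, fell. With all libraries 5 of 358 were lower, Zfp874b, Zfp677, Zfp799, Zfp608 and Zfp36l1, the last an RNA-binding protein gene, and 3 were higher, Zfp703, Zfp142 and Zfp131. Without IGF-1 replicate 5, 37 of 356 (10.4%) were lower, against 3.50% of other genes. Of the 356, 14 were higher, beside 855 of all 15573 genes tested. The group of Zfp genes was picked after such genes were seen among the falls. A test of it on the same calls would therefore not be independent evidence. Many of these genes are paralogs that share sequence.

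IGF-1 replicate 5 differed from replicates 3 and 4 by over 1 on the log2 scale in 12 of 9779 genes of at least 10 CPM, where replicates 3 and 4 differed in 0, as did the controls. The 7 with more in replicate 5 included Aqp1, a water channel gene, at 28.9 CPM against 8.48 and 9.69, and Trf, the transferrin gene, at 59.6 against 24.6 and 25.3. The 5 with less included Scg2, at 4.01 against 10.3 and 13.4, and Slc7a11, the cystine transporter gene, at 5.87 against 15.5 and 15.2. Quartiles of transcript length were formed over another set, the genes with a known length and a mean log2-CPM above 3. Median differences of replicate 5 from replicates 3 and 4, from the shortest quartile, were -0.14, -0.03, 0.01 and 0.06. The SD over genes within each quartile was larger, at 0.23, 0.21, 0.19 and 0.19.

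The log2 changes of the ribosomal protein genes lay below 0, by more in replicate 5 than in replicates 3 and 4. Their median log2 difference between replicate 5 and replicates 3 and 4 was -0.398, while genes matched on transcript length and abundance gave -0.219 (95% of 10000 lists between -0.297 and -0.138). The length trend could thus account for part of it. Whether it accounts for all cannot be told, because the matched genes were longer (median 1060 against 925.5 bases). They were also drawn independently, while the ribosomal protein genes moved together (estimated correlation 0.917), so the range is too narrow. The principal transcript was chosen as the length measure after the longest transcript had given -0.178. With the transcript length offset the list's median over all libraries was -0.122 on the voom scale, against -0.192 without the offset. Without replicate 5 the list's median was -0.0583, near 0, and camera still called it with the preset correlation (adjusted p = 1.91e-07) but not with an estimated one (adjusted p = 0.635), so whether replicate 5 alone makes the pattern cannot be told apart from a small shift in all IGF-1 libraries.

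Genes of ATF4 and amino acid supply were lower in IGF-1 replicate 5 than in replicates 3 and 4, with a median of -0.491. Among them were Slc7a11, Chac1 and Trib3. Genes matched on length and abundance gave -0.0475 (between -0.112 and 0.0167). They were drawn independently, while the genes of the list moved together (estimated correlation 0.755), so this range is too narrow. The matched value itself, far smaller in size than that of the list, argues against the length trend alone. Neurons carried over in the sort would have to dilute the glioma RNA. The 19 low neuronal markers summed to 298 counts in replicate 5 against 230 and 270, a CPM ratio of 1.11. Syt1, a neuronal gene too abundant in these libraries to be among the 19, had 232 counts against 94 and 105. The 19 were chosen by a low mean over all libraries, replicate 5 included, which can leave out markers raised there. The ratio therefore covers these 19 markers only and cannot exclude carried-over neurons. A difference in the culture of replicate 5, such as its amino acid supply, is a hypothesis that was not tested.

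Immediate early genes went up and down after an overnight treatment, Egr1 falling while Egr3 and the EGR corepressor gene Nab2 rose. No value here tells whether handling before lysis differed between the libraries. Of the 10 splits of the 5 libraries into 2 and 3, only 1, the real one, called as many genes: 163 by edgeR, against 0 in the other 9, where 158 to 1360 genes were under 0.05 unadjusted. With 10 splits the share cannot go below 0.1.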
